A study of Drosophila melanogaster with 3 samples.

How the data were processed

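Small RNA of about 18 to 30 nt was purified on gels from Trizol RNA of fly abdomens, ligated to a 3′ and a 5′ adapter, amplified with index primers and sequenced single-end, per the labels' protocols. The deposited values are counts: each line of a library holds a distinct read sequence and the number of times the authors saw it, and its values are whole numbers with no normalization. The trimming tool, any aligner and the genome build were not given in the sources used here. Some sequences or parts of them were in lower case for a reason the sources do not state, and all were read as upper case.

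The hairpin sequence of each transgene was taken from the labels. Reads of 18 to 30 nt were matched exactly and on the sense strand to the hairpin of their library and, for the 5p arm, also to the wild-type hairpin. A read belonged to an arm if it started within 3 nt of the annotated start. Annotation came from Ensembl release 115 (BDGP6.54). A genome sequence was not used here, so other miRNAs could not be counted by genome match. They were counted as reads whose first 18 nt equal those of a mature sequence written down from background knowledge. Of 92 names first written, 82 were kept. Of the 10 left out, 6 differed in length from the annotated arm, 1 had no gene of that name in the annotation and 3 had no read. These 10 names held 127935 reads over the 3 libraries. For 2 of the kept names the sequence was changed by 1 nt to reach the annotated length, after the mismatch was seen. Sequences for the testis list were not held, and that list was not analysed here. The 82 arms are part of the 262 annotated hairpins' products, so a statement on named arms covers these arms alone.

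The scale planned before the data were examined was reads on other miRNA hairpins. Without hairpin sequences the planned fallback, RPM (reads per 1000000 reads of 18 to 30 nt), became the main scale. Ratios between libraries carry exact conditional binomial 95% intervals, levels exact Poisson intervals and shares Clopper-Pearson intervals, and a count of 0 was set to a floor of 3 reads for lower bounds. Arms with at least 50 reads over a pair of libraries were compared, and an arm was counted as different at 2-fold or more with an interval that excludes 1. The 3 pairs were wild-type against mutant-1, mutant-2 against mutant-1 and wild-type against mutant-2. Each group held 1 library, so no p-value was computed. Depth sets the precision: the mutant-2 library held 957427 reads of 18 to 30 nt, against 8416007 and 21432192.

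Named in the text are both miR-277 arms, miR-34-5p, miR-317-3p, arms among the 10 highest and 10 lowest ratios of a pair, among the 10 most abundant of a library, or in a preset list. List medians were placed among 10000 random lists drawn from 5 bins of mean level. Hairpin structures were predicted with RNAfold 2.7.2. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The comparison was tested on simulated Poisson counts with known folds and depths. For wild-type against mutant-2, with 74 arms, 94.2% of 3-fold and 99.7% of 8-fold differences were called in the right direction. Of unchanged arms, 99.4% were left uncalled. The simulation held counting error alone, without PCR copies, variation between libraries or a shift of scale. These shares are therefore not error rates for the calls made here. Alternatives tried were other scales, 1 mismatch, an exact match of the first 18 nt alone, sequences seen at least 2 times, other count minimums and thinning to the shallowest library.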

Results

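Small RNA was sequenced from the abdomens of transgenic Drosophila melanogaster that expressed a miR-277 hairpin strongly in all tissues. The hairpin was the wild-type sequence, a mutant-1 sequence meant to block cutting by Drosha, the nuclear enzyme that releases miRNA hairpins, or a mutant-2 sequence meant to be conservative. The question was how much small RNA each hairpin yields. There were 3 libraries, 1 per transgene, all in the w1118 background, so no difference has a replicate check and no test between groups was made. The intervals given are exact 95% intervals that cover counting error only and leave out variation between animals and libraries. They treat each read as independent. PCR copies cannot be told apart without molecular identifiers, so the intervals may be too narrow even for counting error. The wild-type library held 25113917 reads, the mutant-1 library 9801605 and the mutant-2 library 1079954. Of these, 21432192, 8416007 and 957427 reads were 18 to 30 nt long, so that 3 reads, the floor used for a count of 0, corresponded to 0.140, 0.356 and 3.13 RPM (reads per 1000000 reads of 18 to 30 nt). A library without a transgene was not analysed here. Each library may also hold reads of the endogenous mir-277 gene, which have the same sequence as those of the wild-type transgene. The mutant-1 and mutant-2 libraries held 32 and 5 reads of the 5p arm with the wild-type sequence.

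The mir-277 gene (FBgn0262419) lies on chromosome 3R at 10100022 to 10100121 of the BDGP6 assembly, on the plus strand, inside an exon of the long non-coding RNA CR43459. Its 5p arm is annotated at 10100039 to 10100059 and its 3p arm at 10100080 to 10100102. The mutant-1 hairpin differed from the wild-type hairpin by 4 substitutions in the 5p arm, G21C, T22A, A27C and G28A, with positions counted from 1 at the 5′ end of the hairpin given in the labels. In the structure predicted by RNAfold, 17 of the 23 positions of the 3p arm were paired in mutant-1, against 21 in the wild type. In mutant-2 the changed stretch spans positions 18 to 28, counted on the mutant-2 hairpin itself. That hairpin was 102 nt long instead of 100 nt, so its positions after the change are shifted against the wild type. In it 23 of 23 positions of the 3p arm were paired. The 3p arm and the loop had the same sequence in every construct, so that only reads over the changed positions of the 5p arm tell a mutant transgene from the endogenous gene.

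miR-277-3p, the mature strand of this hairpin, was higher in the wild-type library than in either mutant library. It reached 699.7 RPM (688.6 to 711.0, 14997 reads) in the wild-type library, 160.6 RPM (152.2 to 169.4, 1352 reads) in mutant-1 and 140.0 RPM (117.3 to 165.8, 134 reads) in mutant-2. These are levels of the libraries and not yields of the hairpins, since 3p reads of a transgene cannot be told from endogenous ones. The mutant-1 library held 0 reads specific to its own hairpin, so none of its 1352 reads can be traced to the mutant-1 transgene. The wild-type level was 4.36 times that of mutant-1 (4.12 to 4.61) and 5.00 times that of mutant-2 (4.22 to 5.97). The mutant-2 level was 0.871 times that of mutant-1, with an interval of 0.724 to 1.04 that includes 1, and 0.565 times relative to the median named arm. It was 1.13 times with 1 mismatch allowed, so its direction depended on the setting. The wild-type ratios depended on the scale and the matching. Relative to reads of named miRNA arms they were 7.37 against mutant-1 and 9.65 against mutant-2. Relative to miR-34-5p plus miR-317-3p they were 8.84 and 8.77. That sum is mostly miR-34-5p, with 105366, 87874 and 8889 reads in wild-type, mutant-1 and mutant-2, against 9382, 3530 and 106 of miR-317-3p. miR-317-3p alone was 3.95 times as high in wild-type as in mutant-2. With 1 mismatch allowed the ratios of miR-277-3p were 4.35 and 3.87. Matched on the first 18 nt, as the named arms are, they were 4.32 and 3.81.

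**Figure D1:**
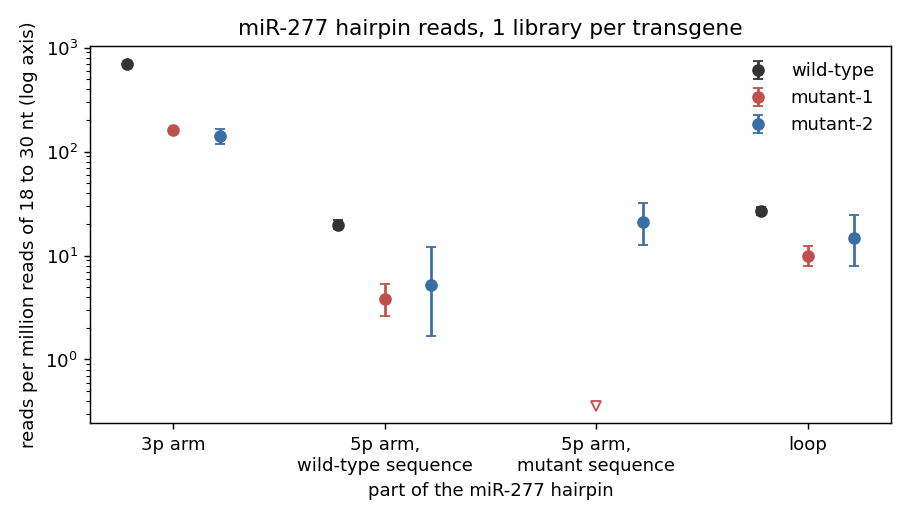
RPM (log axis) for parts of the miR-277 hairpin in the 3 libraries, with exact Poisson 95% intervals as bars; an open triangle marks a count of 0, drawn at the 3-read floor. miR-277-3p stood at 699.7 RPM in the wild-type library, 160.6 in mutant-1 and 140.0 in mutant-2.

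Reads that carry the mutated 5p arm were found for mutant-2 and not for mutant-1. The mutant-1 library held 0 reads over the changed positions of its own hairpin, which allows up to 0.356 RPM by the 3-read floor. The upper end of the exact interval was 0.438 RPM. The mutant-2 library held 24 such reads, or 25.1 RPM (16.1 to 37.3), and the wild-type and mutant-1 libraries held 0 reads of these sequences. Within the 5p arm window, 20 of 25 reads of the mutant-2 library had the mutant sequence (80.0%, Clopper-Pearson interval 59.3 to 93.2%). In the mutant-1 library this was 0 of 32 reads, which allows a share of up to 9.38% by the 3-read floor and 10.9% by the Clopper-Pearson interval. The commonest mutant-2 product of the 5p arm was TCGTACCAGATAGTGCATTTGC, at positions 18 to 39 of the hairpin, with 10 reads.

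The miR-277 5p arm, with both sequences summed, stood at 19.8 RPM in the wild-type library, 3.80 RPM in mutant-1 and 26.1 RPM in mutant-2. The wild-type level was 5.20 times that of mutant-1 (3.63 to 7.71), and the mutant-2 level was 6.87 times that of mutant-1 (3.90 to 12.0). On the other scales these ratios were 5.42 to 10.6 and 4.01 to 7.94. The wild-type level was 0.758 times that of mutant-2, with an interval of 0.506 to 1.18 that includes 1, and the ratio was above 1 on each of the other scales tried, at 1.27 to 1.83. These sums mix origins: 20 of the 25 mutant-2 reads had the mutant sequence, and 0 of the 32 mutant-1 reads did. For the wild-type sequence alone, mutant-2 over mutant-1 was 1.37 (0.418 to 3.55), on 5 against 32 reads. Wild-type over mutant-2 was then 3.79 (1.61 to 11.7). The 5p arm made up 2.75% of the 5p and 3p reads in the wild-type library (2.50 to 3.02%), 2.31% in mutant-1 (1.59 to 3.25%) and 15.7% in mutant-2 (10.4 to 22.3%). The 3p reads in these shares cannot be split between transgene and endogenous gene, so they are not the arm balance of a mutant hairpin alone.

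The 5′ ends of miR-277-3p were alike in the wild-type and mutant-1 libraries and differed in mutant-2. Reads at the annotated 5′ end made up 91.9% of miR-277-3p reads in the wild-type library (91.5 to 92.4%), 92.2% in mutant-1 (90.7 to 93.6%) and 63.4% in mutant-2 (54.7 to 71.6%). In mutant-2, 37 of 134 reads (27.6%, 20.2 to 36.0%) started 2 nt upstream, and 36 of them were the 22-nt read TGTAAATGCACTATCTGGTACG. The wild-type library held 0 of 14997 and the mutant-1 library 0 of 1352 reads with that start. Reads of 23 nt made up 63.7% of miR-277-3p in the wild-type library (62.96 to 64.5%), 55.8% in mutant-1 (53.1 to 58.4%) and 38.1% in mutant-2 (29.8 to 46.8%), where the shifted 22-nt reads lower the share. Among reads at the annotated start they made up 69.3% (68.5 to 70.1%), 60.4% (57.6 to 63.1%) and 60.0% (48.8 to 70.5%). Among reads from the annotated 5′ end, a 3′ part that differed from the hairpin was found in 3.27% of wild-type reads (2.98 to 3.57%), 4.30% of mutant-1 reads (3.26 to 5.54%) and 24.8% of mutant-2 reads (17.1 to 33.8%). An extra T or TT accounted for 22 of the 28 such reads in mutant-2.

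**Figure D2:**
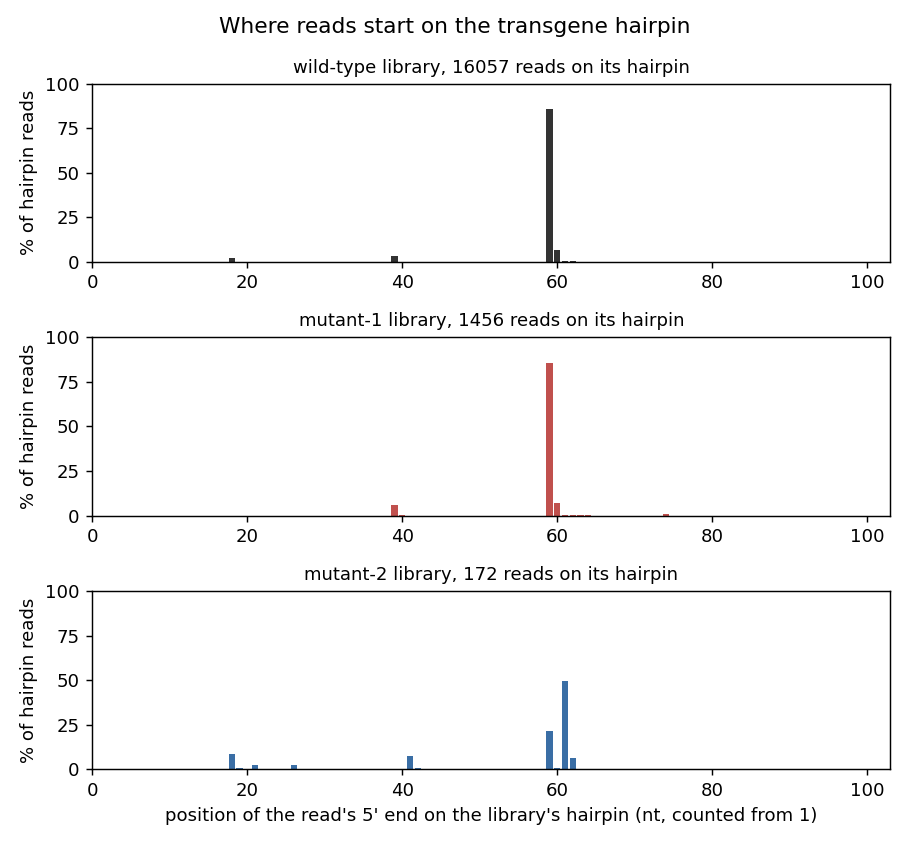
Share of hairpin reads (percent) by the position of their 5′ end (nt from the 5′ end of the library's hairpin), 1 panel per library. The annotated 3p start is position 59 in the wild-type and mutant-1 hairpins and 61 in mutant-2, where a second start at 59 held 37 reads.

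The cluster partners of miR-277 differed between the libraries as well. miR-34-5p and miR-317-3p come from neighbouring hairpins on 3R and are not part of the transgenes. miR-34-5p was lower in the wild-type library (4916 RPM) than in mutant-1 (10441 RPM), with a ratio of 0.471 (0.467 to 0.475), and than in mutant-2 (9284 RPM), with a ratio of 0.530 (0.518 to 0.541). Against mutant-2 this direction turned relative to reads of named miRNA arms, where the ratio was 1.02, and the ratio to mutant-1 was 0.797. The mutant-2 library had 0.889 times the miR-34-5p of mutant-1 (0.870 to 0.909), and 1.02 times when sequences seen once were left out. miR-317-3p was 1.04 times as high in the wild-type library as in mutant-1 (1.004 to 1.085), 3.95 times as high as in mutant-2 (3.27 to 4.83), and 0.264 times as high in mutant-2 as in mutant-1 (0.215 to 0.320). Over the other scales these ratios were 1.09 to 1.77, 6.63 to 9.55 and 0.154 to 0.231.

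The other miRNAs were followed through 82 mature arms named by known mature sequences, not by a genome match. miR-8-3p, which is abundant in fat body and gut, was the most abundant of them in each library, at 51380 RPM in the wild-type library, 112956 RPM in mutant-1 and 54270 RPM in mutant-2. The ovarian miR-989-3p stood at 15978, 17918 and 33580 RPM. Of 75 arms compared between the wild-type and mutant-1 libraries, 12 were at least 2-fold higher and 15 at least 2-fold lower in the wild type, with an interval that excluded 1. These counts were 33 and 6 relative to reads of named miRNA arms. miR-988-3p was 3.85 times as high (3.21 to 4.64) and miR-313-3p 6.26 times (3.78 to 11.1). miR-957-3p had 110 reads against 1, a ratio of 43.2 (7.59 to 1721). miR-308-3p was at 0.0544 times (0.0403 to 0.0723), miR-996-3p at 0.174, miR-79-3p at 0.177, miR-314-3p at 0.270 and let-7-5p, a regulator of developmental timing, at 0.275 times the mutant-1 level. bantam-3p, a growth regulator, was at 0.344 times by reads at its mature start, and at 0.103 times when reads that start up to 7 nt downstream were counted as well.

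Between mutant-2 and mutant-1, 69 arms were compared, and 19 were at least 2-fold higher and 14 at least 2-fold lower in mutant-2. The median arm stood 1.54 times higher in mutant-2, and relative to that median the counts were 10 and 22. miR-315-5p was 8.55 times as high (5.21 to 14.0), the mirtron miR-1010-3p, made by splicing without Drosha, 8.07 times (5.98 to 10.9), miR-286-3p 6.12 times, miR-184-3p 5.18 times and miR-10-5p 4.57 times. The other mirtron compared, miR-1012-3p, stood at 1.12 times, with an interval that includes 1. miR-305-5p was at 0.163 times (0.0526 to 0.386) and miR-304-5p at 0.164 times. miR-986-5p had 0 reads in mutant-2, at least 8.34-fold lower than the 220 reads of mutant-1 when the floor of 3 reads stands in for 0.

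Between the wild-type and mutant-2 libraries, 74 arms were compared, and 12 were at least 2-fold higher and 23 at least 2-fold lower in the wild type. Relative to the median arm, which stood at 0.596, the counts were 21 and 13. miR-305-5p was 8.44 times as high (3.61 to 26.1) and miR-252-5p 5.73 times (3.93 to 8.71). miR-986-5p was at least 16.5-fold higher, with 1108 reads against 0, when the floor of 3 reads stands in for 0. miR-79-3p was at 0.0412 times the mutant-2 level, miR-10-5p at 0.0972, miR-286-3p at 0.107, miR-263b-5p at 0.117 and bantam-3p at 0.177 times, or 0.105 times with downstream starts counted.

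**Figure D3:**
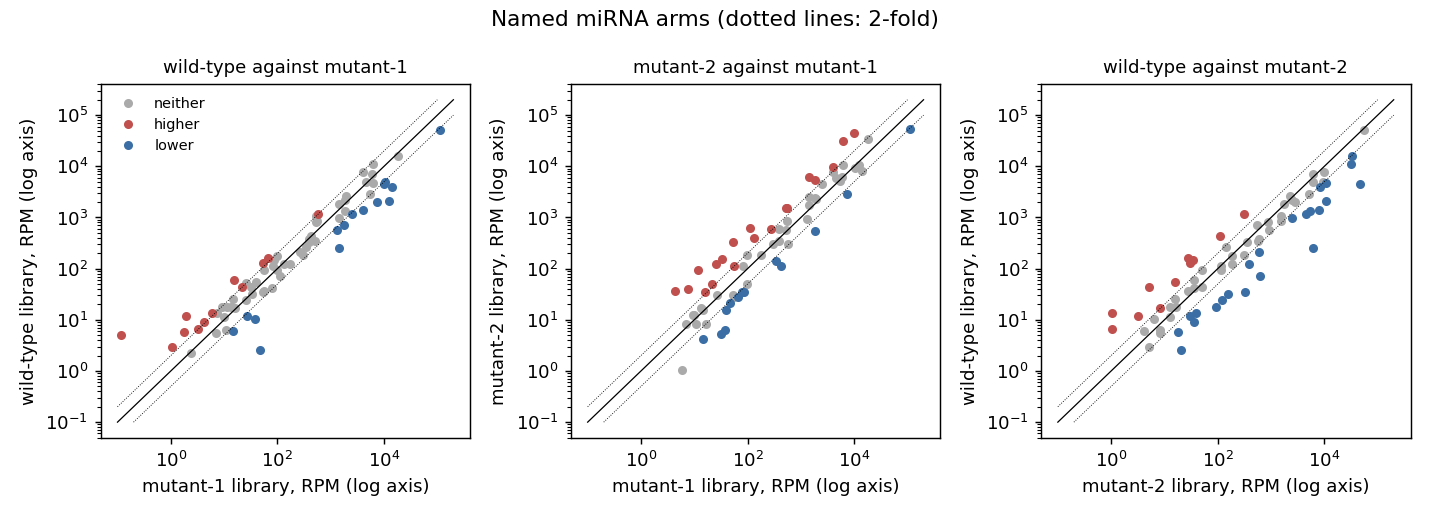
RPM of each named miRNA arm in 1 library against another (log axes), with the solid line at equal levels and dotted lines at 2-fold; arms with reads in both libraries are drawn. Red and blue points are arms at least 2-fold higher or lower with an interval that excludes 1, 12 and 15 of 75 for wild-type against mutant-1 with the arms at 0 reads included.

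The preset lists gave the following medians, each placed among 10000 random lists of the same size and level as a description of these libraries. The 7 ovary arms had a median log2 ratio of 0.61 between wild-type and mutant-1 (84.3rd percentile), with 5 above and 1 below 1. The 6 compared between mutant-2 and mutant-1 had 0.62 (71.4th percentile), and the 7 between wild-type and mutant-2 had -0.07 (70.5th percentile). Relative to the median arm these 2 medians were -0.0011 and 0.68, so their direction depended on the scale. For the 3 nervous system arms the medians were 0.07 (37.2nd percentile), 2.24 (95.9th percentile) and -2.04 (3.75th percentile) in the same order. There miR-124-3p, enriched in neurons, was 4.72 times as high in mutant-2 as in mutant-1 (3.74 to 5.93) and miR-137-3p 0.513 times (0.217 to 1.04). The 5 early embryo arms had medians of -0.61 (3.54th percentile), 1.02 (90.0th percentile) and -0.42 (27.8th percentile), and relative to the median arm the last 2 were 0.39 and 0.33.

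For the 3 let-7 complex arms the medians were 0.42 (72.7th percentile), -0.76 (30.2nd percentile) and 0.09 (80.7th percentile), with let-7-5p opposite in direction to miR-125-5p between wild-type and mutant-1. The 5 fat body and gut arms had 0.42 (84.6th percentile), -0.16 (15.5th percentile) and -0.01 (84.6th percentile), the last of which was 0.74 relative to the median arm. The 2 mirtron arms compared, of 5 held, had -0.27 (20.7th percentile), 1.59 (91.6th percentile) and -1.86 (5.12th percentile). They disagreed in the first pair, with 1 above and 1 below 1. In the second pair 1 was above 1 and 1 had an interval that includes 1. The muscle arms miR-1-3p and miR-133-3p had 1.33 (92.5th percentile) between wild-type and mutant-1 and -0.98 (26.1st percentile) between wild-type and mutant-2. The cluster pair miR-34-5p and miR-317-3p had -0.51 (45.7th percentile), -1.05 (2.58th percentile) and 0.53 (90.0th percentile). On that scale every list median lay 0.63 lower between mutant-2 and mutant-1 and 0.75 higher between wild-type and mutant-2.

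The makeup of the libraries differed too. Named miRNA arms held 14.4% of reads of 18 to 30 nt in the wild-type library, 24.4% in mutant-1 and 27.8% in mutant-2. 5S rRNA held 6.13%, 4.55% and 1.09%, 2S rRNA 1.26%, 0.418% and 0.683%, and reads made of G alone 2.29%, 2.59% and 0.0527%. Reads left without a class were 75.8%, 68.1% and 70.3%. The commonest length was 18 nt in the wild-type library (18.4% of reads), 23 nt in mutant-1 (18.4%) and 22 nt in mutant-2 (19.9%). Among reads without a class, those of 23 to 29 nt, the range of piRNAs, held 13.1%, 16.7% and 22.9%, and 35.7%, 41.5% and 47.0% of these began with T. Most of them were 23 or 24 nt long, as miRNAs can be, and reads of 25 to 29 nt held 1.14%, 1.79% and 4.20%.

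**Figure D4:**
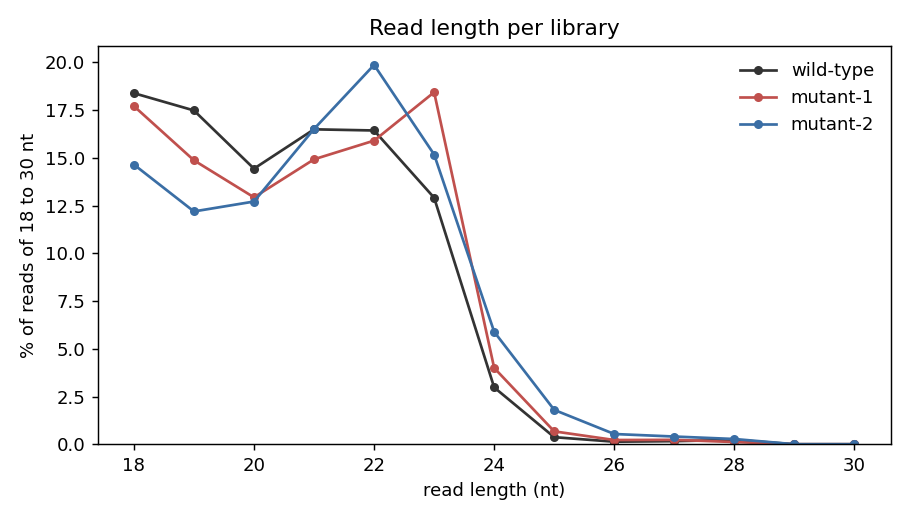
Share of reads of 18 to 30 nt (percent) at each read length (nt), 1 line per library. The highest points are 18.4% at 18 nt in the wild-type library, 18.4% at 23 nt in mutant-1 and 19.9% at 22 nt in mutant-2.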

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

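The tests in this part were chosen after the patterns were seen. Reads of 17 nt lie outside the selected range and entered only the class shares over all lengths. In the wild-type and mutant-1 libraries, reads with miR-277 hairpin sequence among them still lay above the limit a count of 0 allows. In the mutant-2 library the count of such reads lay below this limit. There were 106 such reads in the wild-type library, 72 in mutant-1 and 2 in mutant-2, on the library's own or the wild-type hairpin. The 2 reads of mutant-2 were specific to the mutant-2 hairpin, and 0 of the 72 reads of mutant-1 were specific to the mutant-1 hairpin.

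In the mutant-2 library 37 miR-277-3p reads started 2 nt upstream of the annotated start. A background read made in every library is argued against, since the upper limit of its share in the wild-type library was 0.0246%, against a lower limit of 20.2% in mutant-2. If the mutant-2 hairpin were also cut in a second register, a 5p partner with 2-nt 3′ overhangs would lie at positions 21 to 42, and 3 reads of that sequence, TACCAGATAGTGCATTTGCACT, were found. The same rule applied to the annotated register named a partner that had 0 reads, so the rule misses products that end 1 nt short, such as the 10 reads at 18 to 39. Amplification of a single molecule stays open, because 1 sequence held 97.3% of the shifted reads and there are no molecular identifiers, so a second register is a hypothesis that may explain the shift.

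Reads that started 2 to 7 nt downstream of the mature start made up at least 10% in 1 of 46 arms in the wild-type library, 3 of 35 in mutant-1 and 3 of 23 in mutant-2. In this count the miR-2 family had 65.8% already in the wild-type library, against 81.3% in mutant-1 and 81.7% in mutant-2. Its wild-type reads at the mature start were 67773 here, against 154050 in the main count of named arms. These are therefore not shares of the whole family. miR-13b-3p held 328 wild-type reads here, against 47173 in the main count, and was not among the 46 arms. For bantam-3p the reads that started downstream were 2.67% in the wild-type library, 60.1% in mutant-1 and 43.1% in mutant-2. For miR-275-3p they were 0.516%, 2.78% and 24.3%. Random breakage of all miRNAs is argued against, since the median share over 35 arms was 0.903% in mutant-1, while miR-1-3p stood at 0.186%. A library preparation that differed between the wild-type and the mutant libraries cannot be told apart from the transgene, because each group holds 1 library, and this keeps the bantam share of 60.1% open. No biological explanation was tested.

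Reads of miR-277-3p that ended in T where the mature sequence has another base were 1.84% in the wild-type library, 2.92% in mutant-1 and 19.5% in mutant-2. The ratio between mutant-2 and wild-type was 10.6 (6.501 to 16.3). More T addition on all miRNAs of the mutant-2 library is argued against as the whole cause: counted in the same way, the median ratio over 29 other arms was 1.52 (1.24 to 1.82). The highest was 3.98, and the upper limit lay below 6.501 for 24 of them. Bases beyond the mature end were left out, since without hairpin sequences a templated T cannot be recognised there. The mutant-2 share rests on 22 of 113 reads. A link to the fully paired mutant-2 stem may be considered as a hypothesis, and it was not tested.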

How the results depend on the processing

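The scale of named miRNA arm reads and the count with downstream 5′ ends were chosen after the data were seen, and the others before. miR-277-3p was higher in the wild-type library than in both mutant libraries under every alternative run. The mutant-1 count of specific reads stayed 0 with 1 mismatch allowed and with the first 18 nt matched alone. Its other alternatives rescale the count or remove reads, so they could not have raised a count of 0. Of the alternative values, 101 stayed within their interval or limit, 86 moved and 3 turned a ratio whose interval excluded 1. The 101 include these fixed values of 0. Among the values that stayed or moved, 11 lay on the other side of no difference from a ratio whose interval included 1 or from a list median. These were miR-277-3p in mutant-2 over mutant-1, the 5p arm in wild-type over mutant-2, and the ovary, early embryo and fat body and gut lists. The cause was not tested for any of them. No paired analysis was possible because each group holds 1 library. Left unrun were single-gene reads, which need hairpin sequences, and a changed class priority. The first-18-nt match is already the main count of miR-34-5p and miR-317-3p. Depth limits mutant-2 most, with a floor of 3.13 RPM.

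Relative to reads of named miRNA arms, wild-type over mutant-1 was 7.37 for miR-277-3p, 8.81 for its 5p arm, 0.797 for miR-34-5p and 1.77 for miR-317-3p. Wild-type over mutant-2 was 9.65, 1.46, 1.02 (turned) and 7.63 in that order, and miR-34-5p in mutant-2 over mutant-1 was 0.779. Mutant-2-specific reads were 90.2 per 1000000 of these reads. Arms at least 2-fold higher and lower were 33 and 6 for wild-type over mutant-1 and 27 and 12 for wild-type over mutant-2.

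Without miR-8-3p in that scale, wild-type over mutant-1 was 6.15 for miR-277-3p, 0.665 for miR-34-5p and 1.47 for miR-317-3p. Mutant-2 over mutant-1 was 0.509, 0.520 and 0.154 for these. Wild-type over mutant-2 was 12.1, 1.28 (turned) and 9.55 for these, and 1.83 for the 5p arm. Specific reads were 112.0 per 1000000 of them. Arms higher and lower were 25 and 7 for wild-type over mutant-1, 10 and 23 for mutant-2 over mutant-1, and 36 and 10 for wild-type over mutant-2. Relative to miR-34-5p and miR-317-3p, wild-type over mutant-1 was 8.84 for miR-277-3p and 10.6 for the 5p arm, and wild-type over mutant-2 was 8.77 and 1.33.

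With the median ratio of named arms, wild-type over mutant-1 was 0.491 for miR-34-5p and 1.09 for miR-317-3p. Mutant-2 over mutant-1 was 0.565 for miR-277-3p, 0.576 for miR-34-5p and 0.171 for miR-317-3p. Wild-type over mutant-2 was 8.39 for miR-277-3p, 1.27 for the 5p arm, 0.888 for miR-34-5p and 6.63 for miR-317-3p. Arms higher and lower were 10 and 22 for mutant-2 over mutant-1 and 21 and 13 for wild-type over mutant-2. With the wild-type library as base, specific reads were at 14.9 RPM. The list medians (log2) for mutant-2 over mutant-1 and wild-type over mutant-2 were 0.39 and 0.33 for early embryo, -0.78 and 0.74 for fat body and gut, -1.39 and 0.84 for let-7 complex, -1.67 and 1.28 for the cluster, 0.96 and -1.11 for mirtrons, 1.61 and -1.30 for nervous system, -0.0011 and 0.68 for ovary. Muscle had -0.23 for wild-type over mutant-2.

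With sequences seen at least 2 times, miR-34-5p was 0.476 for wild-type over mutant-1, 1.02 (turned) for mutant-2 over mutant-1 and 0.467 for wild-type over mutant-2. With 1 mismatch, it was 0.918 for mutant-2 over mutant-1 and 0.514 for wild-type over mutant-2, and miR-277-3p was 1.13 and 3.87. Matched on the first 18 nt, miR-277-3p was 1.14 for mutant-2 over mutant-1 and 3.81 for wild-type over mutant-2. Thinned to the shallowest library, 7 arms were higher for wild-type over mutant-2. Over all lengths, wild-type, mutant-1 and mutant-2 shares were 12.3%, 20.9% and 24.7% for named arms, 1.54%, 0.476% and 0.733% for 2S rRNA, 5.50%, 4.07% and 1.02% for 5S rRNA, and 2.43%, 2.84% and 0.0588% for G alone. With distinct sequences counted once, the commonest lengths were 21, 18 and 21 nt.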

Other observations

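The loop of the miR-277 hairpin, which is cut out between the arms, was itself seen in each library. Its sequence is the same in every construct, so its reads cannot be told from those of the endogenous gene. The mutant-1 library held 0 reads specific to its own hairpin, so its loop reads do not show that this hairpin was cut. Loop reads stood at 26.7 RPM in the wild-type library (24.59 to 29.02), 9.86 RPM in mutant-1 (7.86 to 12.2) and 14.6 RPM in mutant-2 (7.99 to 24.5). As a share of loop and 3p reads they were 3.68% (3.39 to 3.99%), 5.78% (4.63 to 7.12%) and 9.46% (5.27 to 15.4%). The commonest loop read was the 20-nt CTGAAACTATCTGAAGCATG, at 25.7 RPM in the wild-type library (550 reads), 9.62 RPM in mutant-1 (81 reads) and 12.5 RPM in mutant-2 (12 reads).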
